A study of Mus musculus with 4 samples.

How the data were processed

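RNA of 2 control and 2 3MC+TPA-exposed C3H10T1/2 samples was read on 4 arrays of a custom mouse design, in 1 colour (Cy3). Per the labels, cells were exposed to 3MC and then TPA and cultured for 6 weeks in all, RNA was labelled by amplification from a T7 promoter, and, per the series' design text, labelled RNA was hybridised in duplicate and analysed in GeneSpring GX 11.5 with a test per gene whose threshold is not given in the sources used here. Groups were taken from the sample titles. Nothing in the labels says whether the 2 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. All 4 arrays lie on 1 slide with 1 scan, the control arrays in the first positions and the exposed in the next, so position on the slide and group cannot be told apart, and no slide block could be run.

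Per the file headers, Agilent Feature Extraction 10.7.3.1 made the intensity values of each spot: the processed signal is the spot's brightness after background subtraction and detrending within the array, with a substitute value for dim spots. The mean and background signals are unprocessed intensity, per the file headers. The deposited table of the whole series holds log2 values made by the authors. Set against the scanner files, each of its columns equals log2 of the processed signal minus the array's 75th percentile, with at least 61236 of 61307 probes equal within 0.01. Its genes are not centred, its direction is that of the scanner signal, and its column medians are -4.29 and -4.31 for the control arrays and -4.39 and -4.35 for the 3MC+TPA arrays. These values served as an alternative.

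The main values are log2 of the processed signal minus each array's 75th percentile over non-control spots (signals of 538.9, 594.0, 698.5 and 744.6 on control arrays 1 and 2 and 3MC+TPA arrays 1 and 2). The 1319 control spots of each array were left out, as were spots flagged as outliers (42, 20, 31 and 68 on these arrays), and no spot was saturated. Spots of 1 probe were averaged: 50 probes have 8 spots each. A feature is a gene name of the files, read by the probe with the highest mean signal over the 4 arrays. A feature was tested when this probe was well above background, by the scanner's flag, on both arrays of at least 1 group, which left 24977 of 50090 features, 7677 of them in the non-coding transcript set. Of the tested features, 58 lacked a value on an array and were left out of the list tests. Symbols are those of the files, updated where the probe's RefSeq accession is in a gene table of assembly GRCm38.p6, which held 28136 of the 61307 probes' accessions. The array's own grid was drawn on another build (mm9), so no coordinates are given, and the table served for names and for which genes share a chromosome.

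Groups were compared with limma 3.58.1 (lmFit and eBayes, 2-sided, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05, alone and with a change of at least 2-fold. The errors given beside a log2 change are standard errors of this fit. A probe not well above background on either array of a group has only a bound there, given as an at-least fold. Such a bound holds for the main values and not under every alternative. The smallest log2 change over the alternatives was -5.73 for Il1rn, -6.02 for Mmp13 and 2.98 for Tceal5, each short of the bound given below. Gene lists (27, 566 symbols, of which Ugt1a6a, Prl2c2 and Prl2c4 had no match on the array) were tested with camera at its preset correlation of 0.01, adjusted over the lists with at least 5 tested members. No list call held with an estimated correlation, which 4 arrays determine poorly. The lists, the tests and the rule for the genes named were fixed before the data were examined. The rule took the 5 largest rises and falls among called genes well above background on all 4 arrays with groups that do not overlap, the 3 largest rises and falls by at-least fold, per list up to 3 called members with the largest change or else the member with the largest change, and Cyp1a1, Cyp1b1, Cdkn1a, Myc, Mki67 and Mmp3. Not every gene the rule selects is named in the text. Ifit2, Rsad2, Ddx58, Ccl20, Tiparp and B2m were named outside this rule, after the values were seen, to complete a count or to give a member that did not pass; genes of the closing section were also chosen so.

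The fit was tested on simulated data: in 24919 features with the arrays' own means and spreads, 200 were changed by known folds. Of 50 features each, 1 was recovered at 2-fold, 22 at 4-fold, 36 at 8-fold and 37 at 16-fold, all with the right sign, with 1 false call among the unchanged features and 0 in a simulation with no change. The data held far more called features (3935) than the 200 changed here, so the adjusted threshold was stricter in the simulation. It also took each feature's spread over the 4 arrays as exact. The recovered numbers therefore do not measure the sensitivity of the comparison itself. Of 867 called features with several tested probes, 548 had every probe called the same way, 4 had a probe called the other way, and 836 had the same sign in every probe. The alternatives tried were normexp background correction, quantile scaling, the median of probes above background, no scaling, spike-in scaling, other filters and probe choices, outlier spots kept, a trended robust variance model, the methods' t-test, the deposited values, the replicate number as a block, each array left out in turn, and other list tests.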

Results

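RNA was measured in C3H10T1/2 cells, an immortalised mouse embryo fibroblast line that stays contact inhibited in culture and is used to score chemically induced transformation. The 2 control arrays held RNA of cells cultured for 6 weeks. The other 2 arrays held RNA of cells exposed to 3-methylcholanthrene (3MC), a polycyclic aromatic hydrocarbon that initiates tumours, at 2.5 µg/ml for 2 days, and later to 12-O-tetradecanoylphorbol-13-acetate (TPA), a phorbol ester tumour promoter, at 100 ng/ml over 2 weeks. These cells then grew for 4 weeks in normal medium before RNA was taken. The study calls them transformed, and the comparison asks which transcripts differed between exposed and control cultures. Each array carried 61657 probe spots for coding and non-coding transcripts, read in 1 colour. On the control arrays 32125 and 32415 spots were well above background, and on the 3MC+TPA arrays 32222 and 32512.

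The largest falls and rises were of genes with varied products, secreted, at the membrane and in the cell. Among genes well above background on all 4 arrays, the largest fall was that of Mmp3, the secreted protease stromelysin 1, at 6.98 ± 0.18 in control and -2.35 ± 0.53 in 3MC+TPA cells (log2 signal relative to the array's 75th percentile, SD, n = 2). Its log2 change of -9.33 ± 0.29 (SE) is 642-fold (limma adjusted p = 0.00026). Next came Igf2, insulin-like growth factor 2, at 500-fold lower, Tenm3 (Odz3 in the files), a teneurin membrane protein, at 267-fold lower, Gas6, a ligand of the TAM receptor kinases, at 220-fold lower, and Gpm6b, a membrane glycoprotein, at 153-fold lower. Their adjusted p lay between 0.00021 and 0.00052. Tenm3 stood at -4.42 and -4.74 on the 3MC+TPA arrays, near their dimmest well-measured signals (-4.81 and -4.79). Over the alternatives its log2 change was as small as -6.32, so its fold depends on the processing. The largest rise was that of F11r, the tight junction protein JAM-A, with a log2 change of 7.10 ± 0.36 (SE) or 137-fold (adjusted p = 0.00084). Msln, the surface protein mesothelin, rose 33.5-fold, Cers4 (Lass4 in the files), a ceramide synthase, 30.1-fold, the homeobox repressor Tgif2 21.8-fold, and Tinagl1, a protein of the matrix, 21.5-fold, with adjusted p between 0.00087 and 0.036. The control arrays stood far apart for Tgif2 (-1.21 and -4.12), Cers4 (-2.57 and -4.33) and Msln (-1.06 and -2.69), so that the log2 change without control array 2 was 3.00, 4.03 and 4.25 for the 3 genes. Without 3MC+TPA array 2 none of these 3 passed (adjusted p = 0.15, 0.057 and 0.051).

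**Figure D1:**
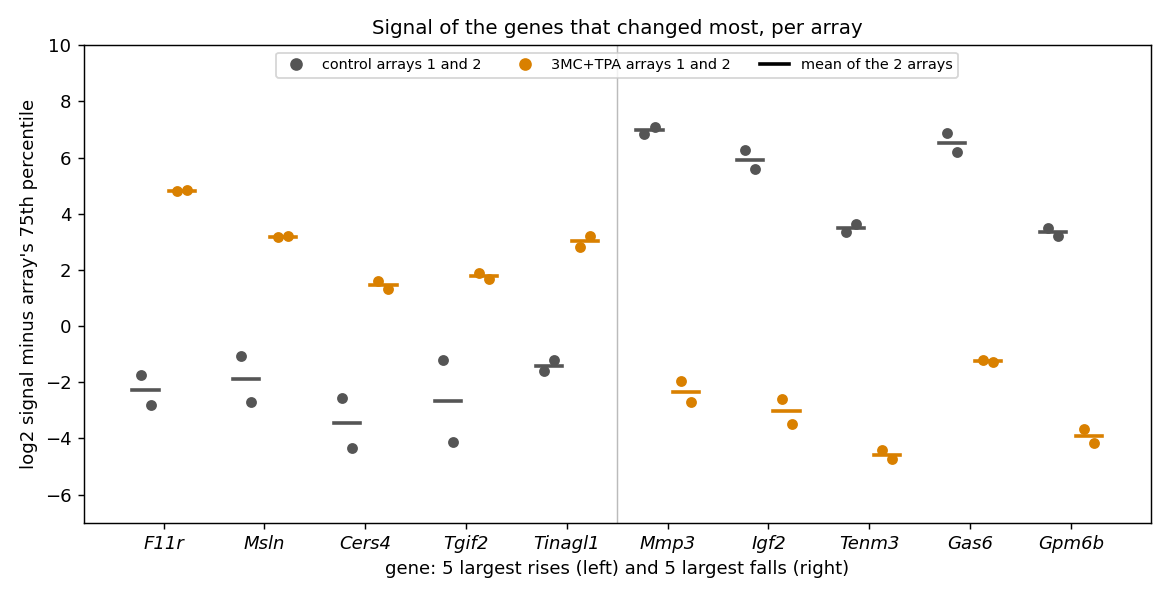
Log2 signal minus the array's 75th percentile (y axis) for the 5 largest rises and 5 largest falls (x axis) on 2 control arrays (grey points) and 2 3MC+TPA arrays (orange points), with the mean of each group as a line. The rule that chose the 10 genes took only genes whose groups do not overlap. Mmp3 spans the largest distance (-9.33), and the control points of Tgif2 lie widest apart.

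Other transcripts passed between background and a measured level. Prl2c5 and Prl2c3, of the proliferin family of prolactin-like secreted proteins, were at least 1310-fold and at least 1050-fold lower in the exposed cells (adjusted p = 0.0021 and 0.0024), where neither array was well above background. On control arrays 1 and 2 Prl2c5 stood at 4.26 and 6.86 and Prl2c3 at 3.88 and 6.59, so these bounds depend on control array 2. The members of this family are near-identical, and their probes may not tell them apart. Il1rn, the interleukin 1 receptor antagonist, was at least 369-fold lower (adjusted p = 0.00033). In the other direction, Cd48, a leukocyte surface receptor, was at least 36.5-fold higher, the kinase gene Nrk at least 26.5-fold higher, and Tceal5, of the TCEAL family of nuclear proteins, at least 23.7-fold higher, with adjusted p between 0.00021 and 0.0023. Such a fold sets the mean of the measured group against, per array, the higher of the dimmest well-measured signal and the probe's own. The p beside it, here and below, comes from the fit to the signals themselves, where dim spots may hold substitute values. On the background side, as for Nrk at -6.95 and -7.06 on the control arrays, it therefore does not measure a spread of RNA levels.

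Of 24977 features tested, 1841 were higher and 2094 lower in 3MC+TPA cells at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 1237 and 1543 of them by at least 2-fold. In the non-coding transcript set, 383 of 7677 features were higher and 510 lower. A larger number, 8404 features, passed an unadjusted 0.05. Both arrays of a group may be hybridisations of 1 RNA sample, so the p-values measure only the spread between these arrays. The count fell from 3935 to 2138 without control array 2, to 1706 without 3MC+TPA array 1 and to 1433 without 3MC+TPA array 2, and stood at 2829 without control array 1. Without scaling between arrays, 79.1% of the called features were higher, against 46.8% in the scaled values.

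Interferon-stimulated genes fell as a group. Of 24 tested, 21 fell and none rose, and the median log2 change was -1.30 (2.46-fold lower). Ifit1, which binds viral RNA, fell 11-fold (log2 change -3.46 ± 0.16, SE), the GTPase gene Mx1 5.41-fold and the ubiquitin-like Isg15 4.58-fold (limma adjusted p = 0.00066, 0.044 and 0.0054). The 3MC+TPA arrays stood apart for Mx1, at -4.24 and -2.55. The 3 members that did not pass were Ifit2 at -0.44, Rsad2 at -0.73 and Ddx58 at -0.37. Counts adjusted over the list alone were 23 lower. The list lay below the other genes (camera adjusted p = 9e-13; adjusted p = 0.64 with an estimated correlation). Genes of MHC class I antigen presentation went the same way, with 8 of 15 lower, none higher and a median of -0.85. The peptide transporter genes Tap1 and Tap2 fell 3.07-fold and 2.44-fold, and the immunoproteasome gene Psmb9 fell 3.03-fold. In the list, 10 fell adjusted over the list alone (camera adjusted p = 4.4e-05; adjusted p = 0.64 with an estimated correlation). B2m, the invariant light chain, changed by -0.25 ± 0.17 (SE), and did not pass.

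Among cytokines and chemokines, 9 of 21 tested members fell and 1, Ccl20, rose, with a median of -0.95. The neutrophil chemokine gene Cxcl5 fell 37.2-fold (log2 change -5.22 ± 0.15, SE) and Cxcl12, ligand of the receptor CXCR4, 22.9-fold, with adjusted p of 0.00021 and 0.00067. Csf2, which encodes GM-CSF, was at least 15.9-fold lower (adjusted p = 0.0022), with no signal well above background in the exposed cells. A total of 10 fell and 4 rose adjusted over the list alone (camera adjusted p = 0.0032; adjusted p = 0.64 with an estimated correlation). Among leukocyte markers, 2 of 9 tested members fell and none rose, the count adjusted over the list alone being the same. They were Cd74, the MHC class II invariant chain, at 4.47-fold lower and the coronin gene Coro1a at 1.86-fold lower (adjusted p = 0.011 and 0.046; list median -0.19, camera adjusted p = 0.35). For Coro1a 1 of 2 tested probes passed, and its call ended in 13 of 20 alternatives.

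Matrix proteases and their inhibitors were lower in part. Of 20 tested, 8 fell and 2 rose, with a median of -0.58. Besides Mmp3, the collagenase gene Mmp13 was at least 211-fold lower and the gelatinase gene Mmp9 at least 12.6-fold lower (adjusted p = 2e-04 and 0.0086), with Mmp9 at -0.47 and -1.83 on the control arrays. Adjusted over the list alone, 10 fell and 3 rose. The call of the list (camera adjusted p = 0.039) ended in 8 of 21 alternatives, among them an estimated correlation (adjusted p = 0.64), without 3MC+TPA array 2 (adjusted p = 0.058), genes well above background on all 4 arrays (adjusted p = 0.18), ranks and second probes (adjusted p = 0.11 each). Extracellular matrix genes also lay lower, with 7 of 26 down, 1 up and a median of -0.20. The proteoglycan gene Lum fell 13.5-fold, the collagen gene Col6a3 8.66-fold and the thrombospondin gene Thbs2 4.76-fold (adjusted p between 0.00094 and 0.0024). Counts adjusted over the list alone were 9 lower and 1 higher (camera adjusted p = 0.023; adjusted p = 0.64 with an estimated correlation, 0.13 without control array 1, 0.31 in second probes and 0.062 by fry).

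Integrins and cadherins were the 1 list called higher. Of 19 tested, 7 rose and none fell, with a median of 0.52. Cdh13, a cadherin anchored by a lipid tail, rose 18.9-fold, the laminin-binding integrin gene Itga7 9.88-fold and the neural adhesion molecule gene Ncam1 7.37-fold (adjusted p = 0.011, 0.0014 and 0.036). Of 6 tested probes of Ncam1, 3 were called higher and none lower. Without control array 2 the log2 change was 3.38 for Cdh13 and 1.98 for Ncam1, and without 3MC+TPA array 2 neither passed (adjusted p = 0.078 and 0.13). In the list, 9 rose and 3 fell adjusted over the list alone. The call of the list (camera adjusted p = 0.023) ended with an estimated correlation (adjusted p = 0.64), without 3MC+TPA array 1 (adjusted p = 0.051), without scaling between arrays (adjusted p = 0.072) and in second probes (adjusted p = 0.38).

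Growth factor genes fell more often than they rose. Of 31 growth factors and receptor tyrosine kinases, 14 fell and 3 rose, with a median of -0.27, and the same list held the falls of Igf2 and Gas6. Hgf, hepatocyte growth factor, fell 45.3-fold (log2 change -5.50 ± 0.20, SE; adjusted p = 0.00035). A total of 14 fell and 6 rose adjusted over the list alone. The list passed narrowly (camera adjusted p = 0.048) and did not in 8 of 21 alternatives, among them an estimated correlation (adjusted p = 0.64), without control array 2 (adjusted p = 0.054), without 3MC+TPA array 2 (adjusted p = 0.058), ranks (adjusted p = 0.14) and the authors' deposited values (adjusted p = 0.054).

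Secreted and intracellular inhibitors led the falls among Wnt pathway genes. Of 23 tested, 8 fell and 1 rose, with a median of -0.32. Nkd2, an inhibitor inside the cell, was at least 198-fold lower, and the secreted Wnt-binding proteins Sfrp2 and Sfrp1 were 25.2-fold and 14.0-fold lower (adjusted p between 0.00039 and 0.00084). Adjusted over the list alone, 9 fell and 5 rose. The call of the list (camera adjusted p = 0.039) ended in 12 of 21 alternatives, among them an estimated correlation (adjusted p = 0.64), without control array 1 (adjusted p = 0.22), without 3MC+TPA array 2 (adjusted p = 0.058), genes well above background on all 4 arrays (adjusted p = 0.15) and second probes (median 0.39, adjusted p = 0.85). Among Hedgehog and Notch pathway genes, 5 of 18 fell and none rose. Hhip, which binds Hedgehog ligands at the surface, was at least 48.4-fold lower, the coreceptor gene Boc 4.09-fold and the Notch ligand gene Dll4 3.54-fold lower, with adjusted p between 0.0015 and 0.011. Hhip stood at 0.02 and 1.57 on the control arrays. Counts adjusted over the list alone were 5 lower and 3 higher (median -0.21, camera adjusted p = 0.18). Of 25 TGF-beta and BMP pathway genes, 5 fell and 3 rose. The BMP antagonist gene Grem1 fell 13.2-fold and the TGF-beta binding protein gene Ltbp2 7.01-fold, while Ccn2 (Ctgf in the files), a matricellular protein, rose 5.23-fold (adjusted p = 0.00084, 0.0011 and 0.0033). In the list, 6 fell and 3 rose adjusted over the list alone (median -0.17, camera adjusted p = 0.35).

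The RNA taken 4 weeks after TPA was also read for targets of the aryl hydrocarbon receptor, which 3MC binds. Of 6 tested, 2 fell and none rose over all features tested: Ahr itself by 1.56 ± 0.33 on the log2 scale (SE, adjusted p = 0.036) and the quinone reductase gene Nqo1 2.46-fold (adjusted p = 0.0081). Cyp1b1 changed by -0.82 ± 0.21 (SE, adjusted p = 0.065), and Cyp1a1 was not well above background on any of the 4 arrays. A total of 3 fell and 1, Tiparp, rose adjusted over the list alone (median -0.70, camera adjusted p = 0.11). Tiparp, a direct target, stood at 0.65 ± 0.17 (SE, adjusted p = 0.060 over all features). NRF2 and glutathione genes lay lower, with 6 of 20 down, none up and a median of -0.56. The glutathione transferase genes Gsta3 and Gsta1 fell 97.0-fold and 43.6-fold, and Gsta2 was at least 23.5-fold lower (adjusted p = 2e-04, 0.0014 and 0.0047). These 3 genes are close paralogs, and cross-hybridisation was not tested. Adjusted over the list alone, 9 fell and 1 rose (camera adjusted p = 0.00049; adjusted p = 0.64 with an estimated correlation).

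Of 19 p53 targets, 4 fell and 2 rose. The death receptor gene Fas fell 6.46-fold and the receptor gene Eda2r 3.71-fold, while Perp, a desmosome protein, was at least 2.40-fold higher (adjusted p = 0.0038, 0.020 and 0.035). Cdkn1a, the p53-induced cell cycle inhibitor, changed by -0.51 ± 0.29 (SE, adjusted p = 0.28). Counts adjusted over the list alone were 4 lower and 2 higher (median -0.33, camera adjusted p = 0.13).

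DNA replication genes lay lower in the exposed cells. Of 25 tested, 4 fell and none rose, and 18 fell adjusted over the list alone, with a median of -0.91. The polymerase gene Pola1 fell 3.23-fold, the origin licensing gene Cdc6 2.84-fold and the helicase gene Mcm4 2.50-fold (adjusted p = 0.015, 0.031 and 0.035). The list's call (camera adjusted p = 5.3e-06; adjusted p = 0.64 with an estimated correlation) stood beside a gap between the control arrays, with a median for array 1 minus array 2 of -0.65. The median of the list was -1.22 without control array 1 and -0.57 without control array 2. No mitosis gene of 20 passed, also adjusted over the list alone, although the list lay lower (median -0.56, camera adjusted p = 0.039; adjusted p = 0.71 with an estimated correlation). Without control array 2 the median was 0.01 (adjusted p = 0.70), and control array 1 minus array 2 had a median of -1.08. The call also ended in 9 other alternatives, among them without 3MC+TPA array 1 (adjusted p = 0.051) and without 3MC+TPA array 2 (adjusted p = 0.076). The member with the largest change was Ccnb1, cyclin B1, at -0.90 ± 0.56 (SE, adjusted p = 0.32). The proliferation marker Mki67 changed by -0.30 ± 0.31 (SE, adjusted p = 0.55) and Myc by -0.99 ± 0.29 (SE, adjusted p = 0.081).

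Of 20 AP-1 and immediate early genes, 2 rose and 1, Prl2c3, fell. Atf3, a stress-induced transcription factor, rose 5.03-fold and Junb, an AP-1 subunit, 1.65-fold (adjusted p = 0.0044 and 0.034). For Junb 1 of 2 tested probes passed. In the list, 3 fell and 2 rose adjusted over the list alone (median -0.22, camera adjusted p = 0.65). Among endoplasmic reticulum stress genes, 5 of 18 rose and none fell. They included Chac1 at 3.98-fold, Trib3 at 2.92-fold and Herpud1 at 2.33-fold higher, genes induced by unfolded proteins or amino acid shortage (adjusted p = 0.020, 0.038 and 0.047). A total of 7 rose and 2 fell adjusted over the list alone (median 0.28, camera adjusted p = 0.10). None of 21 ribosomal protein genes passed, also adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.13); the largest change was that of Rps2, at -0.57 ± 0.16 (SE, adjusted p = 0.072).

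Metabolic lists held single changes. Of 21 hypoxia and glycolysis genes, 3 fell and 1 rose, the counts adjusted over the list alone being the same: the peptide hormone gene Adm fell 4.00-fold, the lactate exporter gene Slc16a3 2.88-fold and the glycolytic gene Pgk1 2.61-fold (adjusted p between 0.0067 and 0.0076; list median -0.12, camera adjusted p = 0.35). Of 19 cholesterol synthesis genes, 3 fell and 1 rose. The synthesis enzyme genes Nsdhl and Fdft1 fell 2.54-fold and 1.77-fold (adjusted p = 0.026 and 0.033). Adjusted over the list alone, 4 fell and 1 rose (median -0.32, camera adjusted p = 0.079).

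Markers of the lineages that C3H10T1/2 cells can enter, and of other cell types, were read as well. Of 8 adipocyte markers tested, 3 fell and none rose: the adipsin gene Cfd was at least 2.16-fold lower, and the transcription factors Cebpa and Pparg were 5.33-fold and 2.44-fold lower (adjusted p between 0.00094 and 0.011). Counts adjusted over the list alone were 3 lower and 2 higher (median -0.14, camera adjusted p = 0.26). Of 12 osteoblast and chondrocyte markers, 4 fell and 1 rose. Spp1, osteopontin, fell 117-fold, Phex at least 3.27-fold and the chondrocyte factor Sox9 5.01-fold (adjusted p = 0.0013, 0.016 and 0.0043). In the list, 5 fell and 2 rose adjusted over the list alone (median -0.33, or -0.30 with genes at background held at their bound; camera adjusted p = 0.13). Of 16 contractile genes, 3 rose and 1, the calponin gene Cnn1, fell 7.83-fold. Only 1 of the 3MC+TPA arrays was well above background for Cnn1 (-4.82 and -4.54 on arrays 1 and 2), so this fold depends on a dim signal. Tagln, transgelin, rose 2.37-fold and the tropomyosin gene Tpm2 2.08-fold (adjusted p = 0.0070, 0.028 and 0.019 for the 3 genes). A total of 5 rose and 2 fell adjusted over the list alone (median 0.34, camera adjusted p = 0.11). The 8 skeletal muscle markers held 1 rise, Mef2c at 2.81-fold (adjusted p = 0.033), and 2 rises adjusted over the list alone (median 0.34, camera adjusted p = 0.16).

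Of 7 endothelial markers, 2 rose and 1 fell: Plvap, of endothelial diaphragms, rose 6.71-fold, the angiopoietin receptor gene Tek was at least 1.77-fold higher, and Sox17 at least 4.40-fold lower (adjusted p = 0.0039, 0.0089 and 0.0039). Adjusted over the list alone, 3 rose and 2 fell (median 0.26, camera adjusted p = 0.53). Of 5 epithelial markers tested, 1 rose, the keratin gene Krt7 at 4.12-fold (adjusted p = 0.042), which was also the count adjusted over the list alone; it stood at -4.37 and -3.00 on the control arrays. The median of this list was -0.03 while its mean was 0.40 and its test pointed higher (camera adjusted p = 0.53).

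**Figure D2:**
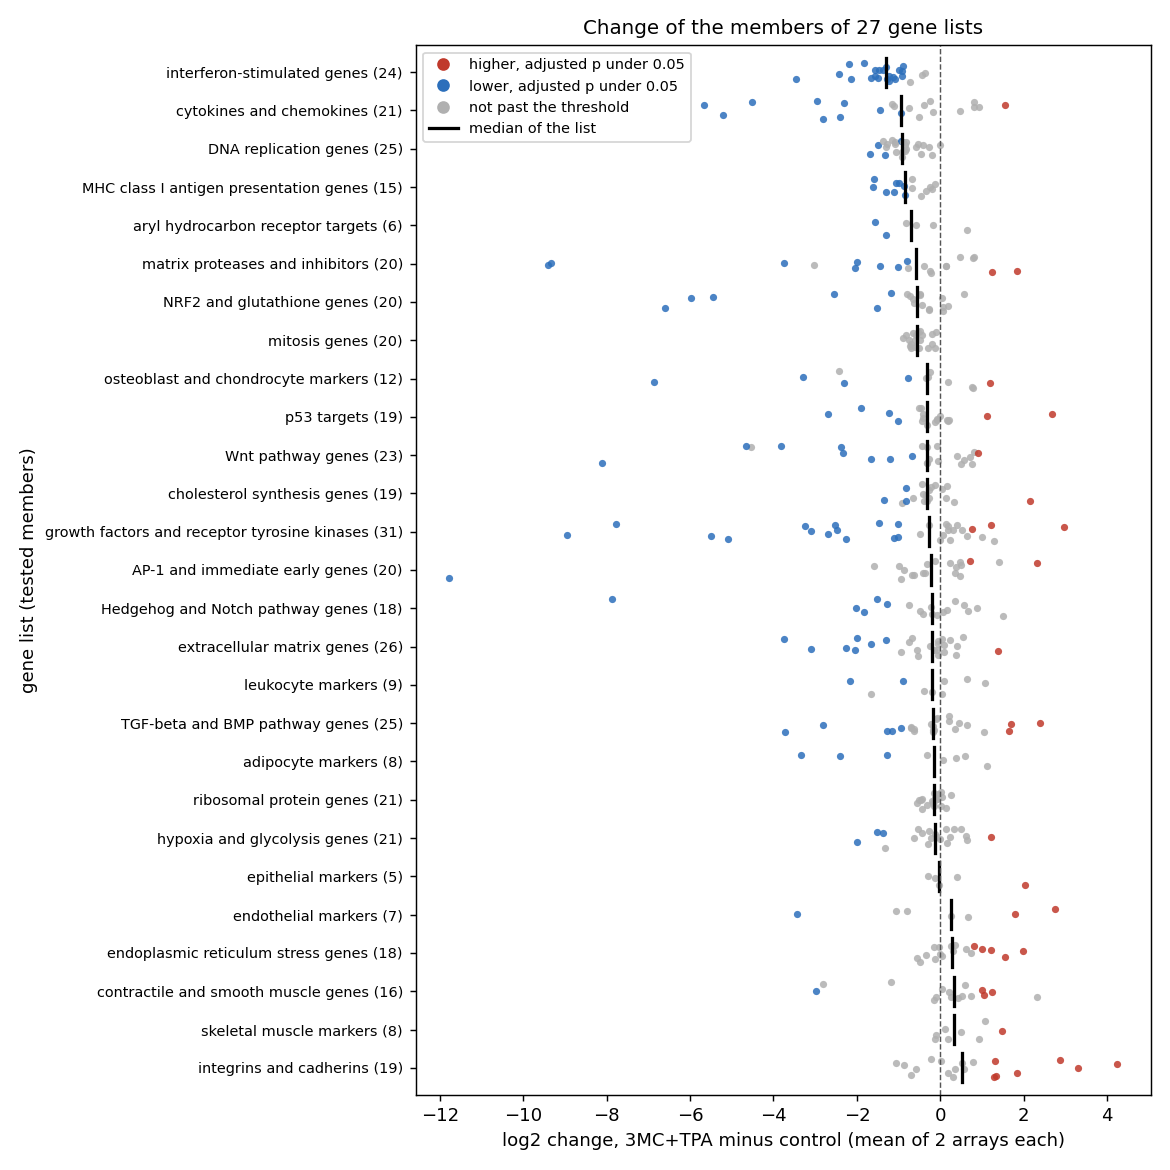
Log2 change, 3MC+TPA minus control (x axis), of the tested members of 27 gene lists (y axis, number of tested members in brackets). Each point is a gene, red or blue where it was called higher or lower and grey otherwise, genes at background on 1 side stand at their fitted change, and black lines are list medians, from -1.30 for interferon-stimulated genes to 0.52 for integrins and cadherins.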

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

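Leaving out dim patches of the arrays, and genes on the chromosome of Xist, were the tests chosen after seeing the result; the others were planned. Against 3935 called features (1841 higher, 2094 lower; 1237 and 1543 by at least 2-fold), counts moved with the number of arrays, the scaling and the filter. With 1 array left out in turn, the lone array of a group being assumed to vary like the other group, 1433 to 2829 features were called, 662 to 1151 higher and 771 to 1678 lower, with the same ranges by at least 2-fold. With no scaling 6725 were called (5321 higher, 2735 by at least 2-fold) and the median over all features moved to 0.34. Spike-in scaling, which moved it to 0.11, called 2267 (1111 higher, 1156 lower); the spike-in spots of 3MC+TPA array 2 averaged 12.95 against 12.21 to 12.38 on the others. With no filter, over 50090 features, 932 were called (346 higher, 586 lower, the same by at least 2-fold). The second brightest probe, for 5582 features, gave 872 (455 and 417; 309 and 319 by at least 2-fold). Normexp gave 696 higher by at least 2-fold. The methods' t-test called 5697 without adjustment and 21 with Benjamini-Hochberg (9 higher, 12 lower; 5 and 10 by at least 2-fold). The replicate number as a block gave 3472, but the numbers did not pair the arrays (correlation of 0.01 between same-numbered differences). Leaving out dim patches gave 4153 features but 8 lists, as the calls of matrix proteases (adjusted p = 0.053), Wnt pathway genes (0.061) and growth factors (0.053) ended.

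Of 27 lists, 10 were called lower and 1 higher. An estimated correlation gave 0 (0 higher, 0 lower). The median of probes above background gave 7 (6 lower), the second brightest probe 7 of 21 (0 higher), no scaling 0 higher, normexp and no filter 3 higher each, the filter on all 4 arrays 2 higher, and fry 8 by direction and 22 in its mixed test. With 1 array left out, 8 to 13 lists were called, 0 to 3 higher and 7 to 10 lower. By fry's direction the calls of mitosis (adjusted p = 0.51), DNA replication (0.18), extracellular matrix (0.062), Wnt pathway (0.056) and MHC class I genes (0.051) ended. The direction of the list test turned, always short of the threshold, with these medians, some of which kept their sign: mitosis genes (0.01), AP-1 genes (-0.01) and skeletal muscle markers (0.12) without control replicate 2, AP-1 genes with no filter (-0.22), hypoxia genes in second probes (0.06), endothelial markers with no scaling (0.61), and ribosomal protein genes under quantile scaling (0.06). Mki67 stood at 0.14 without control replicate 2, and at 0.05 with no scaling, where all features shift alike, so that this value is no sign of a turn. With each array left out in turn, these values ranged from -1.09 to 0.01 for mitosis genes, -0.31 to -0.01 for AP-1 genes, 0.03 to 0.82 for skeletal muscle markers and -0.75 to 0.14 for Mki67. The cause was not tested. Of 87 named genes tested, 81 were called; the call was lost for 9 and 18 without control replicates 1 and 2, for 26 and 32 without 3MC+TPA replicates 1 and 2, for 41 with no filter, for 10 under spike-in scaling, and under the methods' t-test for 80 with Benjamini-Hochberg and 17 without adjustment. Signal over background limits the rest, since genes at background in a group have only bounds.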

Other observations

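All tests in this part were chosen after the result was seen. Genes were grouped by the letters that begin their symbols, and 408 families with at least 5 tested members were compared with all 11934 genes by a Fisher exact test, adjusted over the families. Tetraspanin genes, which encode membrane proteins that organise surface receptors, were the 1 family with more rises than the rest: 9 of 16 rose and 1 fell (adjusted p = 0.0021). Tspan15 rose by 3.05 ± 0.22 and Tspan12 by 2.30 ± 0.31 on the log2 scale (SE, limma adjusted p = 0.0019 and 0.011), and Tspan2 was at least 6.03-fold higher (adjusted p = 0.0029). The opposite held for 13 families. All 7 guanylate-binding protein genes fell (adjusted p = 1.3e-05), Gbp5 at -2.62 ± 0.17 and Gbp6 at -2.45 ± 0.15 (SE). Of 21 H2 genes, 14 fell (adjusted p = 9.4e-08), among them the class II loading factors H2-DMb1, at -3.11 ± 0.15, and H2-DMa, at -1.80 ± 0.16 (SE). Of 9 Oas genes 6 fell (adjusted p = 0.003). Of 11 Ifi genes, 8 fell and 2 rose (adjusted p = 1e-04 for the falls), the rises being Ifi27, at 1.57 ± 0.24, and Ifi30, at 0.87 ± 0.21 (SE). Some members of the H2 and Oas families are near-identical, and cross-hybridisation of their probes was not tested, nor was that of the Sprr and Ly6 genes below.

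Sprr genes, known from cornified epithelium, fell in 6 of 9 cases (adjusted p = 0.003): Sprr1a at -5.08 ± 0.17 (SE, limma adjusted p = 0.00028), Sprr2a3 at least 28.8-fold and Sprr2f at least 20.7-fold. Of 17 Zscan genes, 8 fell (adjusted p = 0.0038), all of them copies or pseudogenes of Zscan4, known from the early embryo, such as Zscan4e at -3.27 ± 0.48 and Zscan4f at -4.45 ± 0.94 (SE). These copies are near-identical, so how many of them changed is uncertain. For Zscan4f only 1 of the 3MC+TPA arrays was well above background, so the size of its fall depends on a dim signal. Of 15 Ly genes, 1 rose (Ly75, at 0.82 ± 0.19) and 7 fell (adjusted p = 0.0092), the falls all of the Ly6 group of lipid-anchored surface proteins, among them Ly6a, the stem cell antigen Sca-1, at -2.24 ± 0.20, and Ly6c1 at -2.95 ± 0.20 (SE). Of 53 genes whose symbols are H followed directly by a digit (the H2 genes above left out), mostly histones, 14 fell and 1 rose (adjusted p = 0.011). Of these falls 6 were of H4 copies at -1.08 to -0.88, which are near-identical, so the count and its p are uncertain.

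Genes on the chromosome of Xist were lower in 3MC+TPA cells as a set: their median log2 change was -0.65 over 355 genes, against 0.04 over 11213 others, and 137 of them were called lower and 21 higher, against 784 and 961 (Fisher exact p = 7.5e-61 for the lower calls). This p also counts genes as independent, which genes that shift together are not. Medians of the other chromosomes ran from -0.29 (chromosome 16, 56 lower and 11 higher) to 0.26 (chromosome 18, 17 lower and 32 higher). In 10000 random sets of 355 genes the medians ran from -0.08 to 0.18, so other chromosomes shifted too, though less far. Xist itself, the RNA that silences an X chromosome, changed by -1.20 ± 0.17 (SE, limma adjusted p = 0.014), and its 4 probes ranged from -1.20 to -0.93. The tables argue against a few strongly changed genes (the percentage lower exceeded that of other genes by 37.5 points), against 1 control array as the source (-0.68 against the array closest to 0) and against signal level (-0.67 against genes matched in level). Fewer active copies of that chromosome in the exposed cells stays open, with 83.7% of its genes lower, and cannot be told apart from other causes because DNA was not measured. Without the genes on the chromosome of Xist 9 of the 11 list calls stayed, and those of matrix proteases (camera adjusted p = 0.061) and growth factors (camera adjusted p = 0.053) ended. The growth factor list held 0 of these genes, so its p moved only with the genes it was compared with and the adjustment over lists. The lists of NRF2, p53 target, DNA replication, extracellular matrix, matrix protease, hypoxia, cholesterol, and osteoblast and chondrocyte genes each held 1 gene of that chromosome. Without its gene the DNA replication list had a median of -0.90 (camera adjusted p = 1.4e-05). Single genes named above were not set apart by chromosome, so falls of some may be part of this shift.

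Genes risen in 3MC+TPA cells stood higher on control array 1 than on control array 2: of 174 that rose at least 4-fold, 150 did so, by a median of 0.59, while among 304 that fell at least 4-fold 136 did, with a median of -0.07. Noise of single spots would lean to neither array, and the values argue against it for risen genes with a second probe. Over all genes with 2 probes the difference between the control arrays correlated at 0.5 between them (0.36 for the 3MC+TPA arrays). Of 30 risen genes with another probe 23, or 76.7%, were higher on control array 1 in it (exact interval 57.7 to 90.1). Its median difference was 0.28, against 0.02 between the 3MC+TPA arrays, and it correlated at 0.62 with the first probe. The interval leaves out an even split, but its lower end misses the stricter limit set for this test. RNA of exposed cells mixed into control array 1 cannot be told apart from other causes: at the median share of 6.23%, 24.6% of 57 genes lay over 1 log2 unit from the level needed (exact interval 14.1 to 37.8), 13 of the 14 below it, while 2.84% of genes of like level differed so between the 3MC+TPA arrays, and implied shares of most genes ran from 0.095% to 14.1%. The limit of 25% was set first, replaced once the value was seen by a limit that ruled mixing out, and then put back, so the open verdict turns on a narrow margin, and the spread of the shares argues against a common one. Control cultures in different states stay open as well. The number of labels stating that both arrays held 1 RNA was 0, but the labels do not address this, so the count cannot decide it. Mitosis genes differed between the control arrays by a median of -1.08 (array 1 minus array 2), which goes with such states. Whether labelling or hybridisation of 1 RNA could give this gap was not tested.

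On 3MC+TPA array 2, 81 spots lay at least 5 log2 units under the same spot of its partner. In a first test by tiles of 8 rows and 6 columns, 43.2% of them lay in tiles dim as a whole, which left a patch of the array without signal undecided. A second test, made after that value was seen, counted spots with at least 2 other such spots within 4 rows and 4 columns, and 87.7% had them, against at most 7.41% in 1000 random placements, which goes with such a patch. The crowded places covered 361 spots on control array 2, 135 on 3MC+TPA array 1 and 611 on 3MC+TPA array 2. Of the features tested there, 26 of 141, 8 of 51 and 27 of 212 were called, among them Cxcl5, Mcm4 and Slc16a3, while 15.8% of all features were called. No biological explanation was tested, and single spots stood apart elsewhere too, as for Cst3, at 7.77, 7.52, 7.62 and -6.83 on the 4 arrays.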
